A study of Mus musculus with 15 samples.

How the data were processed

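Livers of male C57BL/6 mice were sampled at 40 weeks of age. Per the labels, the mice fell into 5 groups. Nor mice were given PBS and fed chow. NCD mice were injected at 2 weeks of age with DEN (diethylnitrosamine, a liver carcinogen) and fed chow. H1D, H2D and H3D mice were given DEN in the same way and fed a high-fat diet with 60% of its energy from fat. Their mothers, of generation F0 for H1D, F1 for H2D and F2 for H3D, came from a line in which females ate that diet from 1 to 3 months of age, starting with F0. The 3 high-fat groups therefore differ from NCD in their own diet and in their ancestry together, and no group separates these, while the 3 share their own diet. Each generation among them is 1 group, so ancestry cannot be told apart from the cohort in which a group was bred. RNA of 4 to 8 animals per group was combined into 2 pools for long RNA and 1 pool for small RNA, so the spread between pools is not the spread between animals.

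For long RNA the labels describe removal of ribosomal RNA and paired reads of 125 nt. The authors deposited FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for each transcript, in separate tables for mRNA, annotated long noncoding RNA, unannotated long noncoding RNA and transcripts of uncertain coding potential. The labels list Bowtie2 2.0.6, TopHat2 2.0.9, Cufflinks 2.1.1, Cuffdiff 2.1.1, Picard 1.96, SAMtools 0.1.18, GATK and the GRCm38 build, with no order or role given. For small RNA (reads of 50 nt) the authors deposited read counts per mature miRNA and a column that is, by its values, RPM (reads scaled to a common total of listed miRNA reads) with no length term, although it is headed as a length-corrected unit. Mapping of the small RNA reads is not described. The number of long RNA reads per library is not given, so the depth of the FPKM values is unknown and no counting interval was computed for them.

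Transcript values of the mRNA table (50660 transcripts) were summed to 21949 gene identifiers, of which 21676 had a symbol in the gene name table supplied with the files. Genes with at least 1 FPKM in at least 2 libraries were tested (11557 genes). Values were analysed as log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3, with 1 coefficient per group for the 5 groups, a trend of the variance with the mean and 5 residual degrees of freedom. Tests were two-sided, and Benjamini-Hochberg adjusted p below 0.05 within a comparison counted as a call. "Rose" and "fell" are used for calls. The 3 noncoding tables were stacked and tested together in the same way, from 0.5 FPKM in 2 libraries (1493 of 2030 transcripts). Means are given with the SD over the pools of a group, and log2 changes with limma's standard error. The comparisons were NCD against Nor, each high-fat group and the mean of the 3 against NCD, and the high-fat groups against each other.

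Of 40 gene lists fixed in advance, 38 were tested with camera (preset correlation between genes of 0.01, Benjamini-Hochberg over the lists). Camera with an estimated correlation and fry were run beside it. With an estimated correlation, 1 list call held in NCD against Nor and 0 in each of the other comparisons, so each list is given with that adjusted p. A calibration on simulated data, in which 1 list was shifted, returned that list and 0 others. The simulated genes varied independently, so it cannot show whether the preset correlation is large enough for these data. Members are also counted with p "adjusted over the list alone". The small RNA libraries have no replicates. A miRNA was listed when its libraries together held at least 100 reads and its log2 ratio of RPM, with 0.5 added, was at least 1 in size. No p-value was computed, and 95% Poisson intervals for counts cover counting error only. A count of 0 would allow up to 3 reads, or 0.361 to 0.437 RPM. Lists of miRNAs were placed among 10000 random lists of like abundance. Each member was drawn on its own, so a percentile does not allow for miRNAs of a list that vary together. TMM factors came from edgeR 4.0.16. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

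Groups, comparisons, tests, gene lists, the rule for named genes and the other settings listed next were fixed before the data were examined. The rule names the 6 largest rises and 6 largest falls among called genes with a mean of at least 2 FPKM in either group and no overlap between pools, passing over models with only a clone or predicted-gene number. It adds the 4 members with the smallest p of each called list and 16 fixed genes. Some results under this rule are not reported here. Acsl1, Aldh2 and miR-27a-3p were fixed because the published study of these animals followed them. For noncoding RNA it names the 4 largest rises and falls with H19, Meg3, Malat1 and Neat1, and for miRNAs the 5 largest in each direction with 7 fixed miRNAs. Other settings were pseudocounts of 0.1 and 1, no filter, a stricter filter (mean of at least 5 FPKM, or 1 for noncoding RNA), quantile and median-of-ratios scaling, a fit of the compared groups alone, no variance trend, a block for replicate number, each transcript tested on its own, TMM scaling, 5 RPM added and other read minimums for miRNAs, and each pool left out in turn. When a pool is left out, its partner is assumed to vary like the other groups. Scaling to an equal FPKM sum was added after the FPKM sums were seen to differ between groups.

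In simulated data with independent genes, 100 genes were shifted by 1 and another 100 by 2 on the log2 scale. The same fit recovered 65% to 80% of mRNA genes changed by 1 and 87% to 98% of those changed by 2, with 4 to 11 false calls. For noncoding transcripts the shares were 46% to 69% and 86% to 94%, with 5 to 10 false calls. Replicate numbers were checked as pairs across groups. Of 10 correlations between residual profiles, 4 exceeded 0.1 (range -0.053 to 0.225), so the numbers were not used to pair samples. Groups of 2 pools are too small for a test of stray samples or for other splits of the samples.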

Results

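Liver RNA was profiled in 10 long RNA libraries, 2 pools for each of Nor, NCD, H1D, H2D and H3D, and in 5 small RNA libraries, 1 for each group. The sum of mRNA FPKM was 784456 and 772100 in the Nor pools, 676268 and 660821 in NCD, 628484 and 607741 in H1D, 628435 and 608708 in H2D, and 568823 and 582521 in H3D. Mitochondrially encoded genes made up 12.1% and 16.2% of that sum in Nor and 8.66% and 8.27% in H3D. Between 10263 and 11169 genes reached 1 FPKM in a library. The correlation between the pools of a group ran from 0.978 in Nor to 0.991 in NCD. The first principal component held 64.7% of the variance and the second 11.4%. On the first, the Nor pools lay at -69.1 and -60.3, the NCD pools at -9.83 and -13.1 and the H3D pools at 40.9 and 38.4, with H1D and H2D between 11.8 and 23.3. Small RNA libraries, whose values are given in RPM (miRNA reads scaled to a common library total), held 8097887 reads (Nor), 7162150 (NCD), 7579463 (H1D), 8316744 (H2D) and 6864962 (H3D).

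NCD against Nor asks what DEN changed in the liver of chow-fed mice. Oncofetal genes rose. Afp (ENSMUSG00000054932, chromosome 5, 90490714 to 90508907 on GRCm38), the fetal serum protein used as a liver tumour marker, was 0.260 ± 0.139 FPKM in Nor and 32.2 ± 9.21 in NCD (SD, n = 2 pools each). Gpc3 (ENSMUSG00000055653, chromosome X, 52272426 to 52613974), an oncofetal proteoglycan, went from 0.130 ± 0.0277 to 63.1 ± 13.7 FPKM. Of 19 measured tumour and fetal liver markers 14 rose and 0 fell (16 and 0 adjusted over the list alone), with a median log2 change of 2.78 and camera adjusted p = 5.8e-17. This was the 1 list call that held with an estimated correlation (adjusted p = 0.0468). Tff3, a secreted mucosal peptide, rose by 6.06 ± 0.22 on the log2 scale, Akr1c18, a steroid-metabolising reductase, by 7.41 ± 0.29, and Ly6d by 6.85 ± 0.33. Bex1 and the trypsin inhibitor Spink1 were listed at 0 in both Nor pools and reached 7.80 ± 0.487 and 167 ± 104 FPKM in NCD.

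Lists of cell division, interferon response and oxidative defence genes had higher medians in NCD as well. Of 29 interferon-stimulated genes 24 rose and 0 fell (28 and 0 adjusted over the list alone), with a median of 1.06 and camera adjusted p = 5.0e-16 (adjusted p = 0.443 with an estimated correlation). Examples were the nucleic acid sensor Zbp1 (3.60 ± 0.0911 to 11.2 ± 1.65 FPKM), Oas1a (1.87 ± 0.23) and Gbp2 (1.58 ± 0.21). In the cell cycle list 14 of 24 rose and 1 fell (17 and 1 adjusted over the list alone; median 1.01, camera adjusted p = 2.2e-08). That p was 0.443 with an estimated correlation, and the call ended among genes with a mean of at least 5 FPKM (median 0.33, adjusted p = 0.271). The proliferation marker Mki67 was 0.319 ± 0.136 FPKM in Nor and 2.51 ± 0.376 in NCD. Of 20 NRF2 targets, the antioxidant genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.29, camera adjusted p = 0.000817, adjusted p = 0.443 with an estimated correlation). The cystine transporter Slc7a11 rose by 3.47 ± 0.41 and Srxn1 by 1.70 ± 0.17. In the p53 target list 5 of 19 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.47, camera adjusted p = 0.000879, adjusted p = 0.443 with an estimated correlation), among them Phlda3 (2.31 ± 0.27) and Btg2 (1.65 ± 0.20). Without Nor replicate 1 the p53 call ended (median 0.18, adjusted p = 0.0663). Of 24 cholesterol synthesis genes 8 rose and 0 fell (13 and 1 adjusted over the list alone; median 0.70, camera adjusted p = 1.8e-05, adjusted p = 0.462 with an estimated correlation), including Hmgcs1 (1.54 ± 0.29) and Sqle (1.39 ± 0.28).

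Markers of cells other than hepatocytes moved in the same comparison. In the fibrosis and stellate cell list 10 of 27 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.64, camera adjusted p = 3.5e-05, adjusted p = 0.443 with an estimated correlation), such as the smooth muscle actin Acta2 (1.75 ± 0.26) and the collagen Col4a1 (1.24 ± 0.23). In the cholangiocyte list 3 of 8 rose and 0 fell (5 and 0 adjusted over the list alone; median 1.07, camera adjusted p = 9.4e-05, adjusted p = 0.443 with an estimated correlation). These were Tspan8 (0.145 ± 0.0215 to 105 ± 2.48 FPKM), osteopontin, Spp1 (13.8 ± 3.67 to 230 ± 36.7 FPKM), and Krt23. In the macrophage list 3 of 23 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.54, camera adjusted p = 0.000175, adjusted p = 0.509 with an estimated correlation), led by Mpeg1 (1.69 ± 0.10). In the lymphocyte list 3 of 13 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.87, camera adjusted p = 6.4e-05, adjusted p = 0.443 with an estimated correlation), led by the chemokine Ccl5 (2.64 ± 0.28).

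Lists of fatty acid oxidation and of alcohol and aldehyde oxidation genes had lower medians in NCD. Of 27 PPARα targets and fatty acid oxidation genes 16 fell and 1 rose (16 and 1 adjusted over the list alone; median -0.53, camera adjusted p = 1.6e-05, adjusted p = 0.443 with an estimated correlation). Acsl1 (ENSMUSG00000018796, chromosome 8, 46471037 to 46536051), which activates long-chain fatty acids, fell from 514 ± 13.9 to 276 ± 43.3 FPKM (adjusted p = 0.00753). Of 16 alcohol and aldehyde dehydrogenases 7 fell and 1 rose (12 and 1 adjusted over the list alone; median -0.55, camera adjusted p = 0.000175, adjusted p = 0.443 with an estimated correlation). Aldh2 (ENSMUSG00000029455, chromosome 5, 121566027 to 121593824), the mitochondrial enzyme that clears acetaldehyde, was 1492 ± 115 FPKM in Nor and 1095 ± 34.8 in NCD and did not pass the threshold (adjusted p = 0.0502). Of 13 mitochondrially encoded genes 6 fell and 0 rose (9 and 0 adjusted over the list alone; median -0.49, camera adjusted p = 0.000108, adjusted p = 0.443 with an estimated correlation). The lists of fatty acid synthesis (3 of 19 rose and 1 fell, camera adjusted p = 0.101), CAR and PXR type xenobiotic genes (3 of 23 rose and 4 fell, camera adjusted p = 0.101) and glucose metabolism (0 of 29 rose and 1 fell, camera adjusted p = 0.115) did not pass. Of 26 female-biased liver genes 7 rose and 0 fell (8 and 0 adjusted over the list alone; median 1.35, camera adjusted p = 2.2e-05, adjusted p = 0.443 with an estimated correlation). Of 25 male-biased genes 3, Susd4, Slco1a1 and Cyp2d9, fell and 0 rose (3 and 0 adjusted over the list alone; median -0.63, camera adjusted p = 0.0115, adjusted p = 0.560 with an estimated correlation). That list call ended with the stricter filter, with quantile scaling and without Nor replicate 1 or NCD replicate 1. The steroid hydroxylase Cyp2a4 went from 0.455 ± 0.575 to 983 ± 34.9 FPKM, the largest rise under the naming rule. Among the largest falls were those of the lipid transporter Mfsd2a (-2.13 ± 0.34), Eif4ebp3 (-1.96 ± 0.44), the lipolysis inhibitor G0s2 (-1.67 ± 0.25), Pim3 (-1.60 ± 0.19) and Txnip (-1.55 ± 0.27).

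In total 1609 of 11557 genes were called between NCD and Nor, 916 higher and 693 lower, against 3751 at an unadjusted p under 0.05. Of the 16 fixed genes 5 rose, 2 fell and 9 were not called. The count was 256 without NCD replicate 1, 409 without NCD replicate 2 and 725 without Nor replicate 1, and 40 of 89 called named genes kept their call in all 10 fits that left out a pool. It was 652 with quantile scaling, 681 in a fit of these groups alone and 914 when each transcript was tested, and the higher share went from 56.9% to 94.6% with equal FPKM sums, which raised the median of all genes to 0.161.

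**Figure D1:**
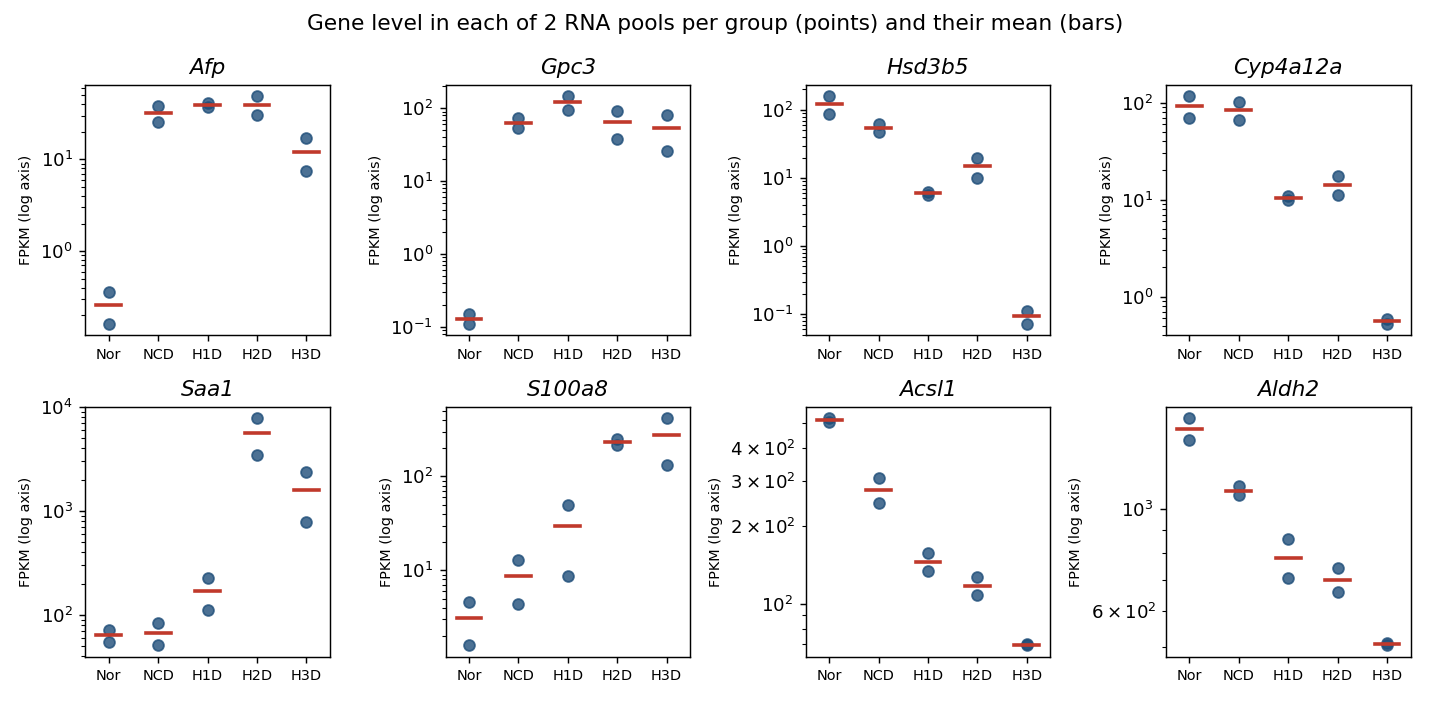
FPKM of 8 genes (log axis) in each of the 2 pools per group (points), with the group mean (bars). Afp and Gpc3 were near 0 in Nor and present in all DEN groups, Hsd3b5 and Cyp4a12a were lower in each high-fat group than in NCD and lowest in H3D, and Acsl1 went from a mean of 514 FPKM in Nor to 69.4 in H3D.

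H1D against NCD compares sons of the first high-fat mothers, themselves on the diet, with chow-fed DEN mice. Genes expressed more in male than in female liver had a lower median. Hsd3b5 (ENSMUSG00000038092, chromosome 3, 98618636 to 98645534), a steroid dehydrogenase of male liver, went from 54.5 ± 9.65 to 5.99 ± 0.386 FPKM, and the fatty acid hydroxylase Cyp4a12a (chromosome 4, 115299046 to 115332815) from 83.5 ± 25.1 to 10.3 ± 0.709 FPKM (SD, n = 2 pools each). Of 25 male-biased genes 12 fell and 0 rose (22 and 0 adjusted over the list alone; median -1.68, camera adjusted p = 1.3e-22, adjusted p = 0.244 with an estimated correlation). Female-biased genes had a median of 0.74 with 0 of 26 called (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.00163, adjusted p = 0.515 with an estimated correlation), and that list call ended without NCD replicate 2 (median 0.154) or H1D replicate 2 (median 0.186). The largest falls were those of the major urinary protein genes Mup15 (-3.64 ± 0.43), Mup17, Mup1, Mup9 and Mup12 and of Cml5 (-3.29 ± 0.21). The Mup genes are near-identical paralogs whose reads can be shared, so the value of any single Mup gene is uncertain.

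Acute phase genes, made by the liver in inflammation, had a higher median in H1D than in NCD. Of 29 members 4 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.51, camera adjusted p = 1.1e-10, adjusted p = 0.244 with an estimated correlation). These were the lipocalin Lcn2 (240 ± 57.4 to 727 ± 25.4 FPKM), Serpina3n (1.28 ± 0.13), Itih3 (0.89 ± 0.09) and ceruloplasmin, Cp (0.80 ± 0.11). In the macrophage list 2 of 23 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.53, camera adjusted p = 3.5e-06, adjusted p = 0.475 with an estimated correlation). In the neutrophil list 1 of 12, Lcn2, rose and 0 fell (1 and 0 adjusted over the list alone; median 0.71, camera adjusted p = 0.00502, adjusted p = 0.529 with an estimated correlation). That list call ended without H1D replicate 2 (median 0.015) and with equal FPKM sums (median 0.752). The called macrophage genes were Mpeg1 (0.79 ± 0.10) and Trem2, a receptor of lipid-associated macrophages (0.842 ± 0.104 to 3.04 ± 0.479 FPKM). The bacterial sensor Pglyrp1 (1.86 ± 0.17), Fos (1.32 ± 0.21) and Map3k6 (1.26 ± 0.15) were among the 6 largest rises.

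Xenobiotic, fatty acid synthesis and fatty acid oxidation genes had lower medians in H1D. In the CAR and PXR type xenobiotic list 4 of 23 fell and 0 rose (11 and 1 adjusted over the list alone; median -0.71, camera adjusted p = 1.3e-08, adjusted p = 0.323 with an estimated correlation), including Cyp1a2 (-2.16 ± 0.29) and Ces2a (-2.01 ± 0.24). In the fatty acid synthesis list 1 of 19 fell and 0 rose (7 and 0 adjusted over the list alone; median -0.64, camera adjusted p = 4.6e-07, adjusted p = 0.266 with an estimated correlation). It was malic enzyme, Me1 (-1.93 ± 0.23). In the PPARα and fatty acid oxidation list 1 of 27 fell and 0 rose (10 and 1 adjusted over the list alone; median -0.33, camera adjusted p = 9.0e-05, adjusted p = 0.508 with an estimated correlation). It was Acsl1 (276 ± 43.3 to 145 ± 16.6 FPKM, adjusted p = 0.0349). Aldh2 was 782 ± 107 FPKM in H1D against 1095 ± 34.8 in NCD and was not called (adjusted p = 0.106).

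In total 81 genes were called in H1D against NCD, 24 higher and 57 lower, with 1986 at an unadjusted p under 0.05. Of the 16 fixed genes 1 rose, 2 fell and 13 were not called. Leaving out NCD replicate 1 or NCD replicate 2 gave 0 calls with limma (1378 and 1125 genes at an unadjusted p under 0.05), H1D replicate 1 gave 2, H1D replicate 2 161, Nor replicates 1 and 2 183 and 184, H2D replicates 1 and 2 38 and 40, and H3D replicates 1 and 2 31 and 52, so that 0 of 27 called named genes kept their call in all 10 fits. The count was 52 with a pseudocount of 0.1, 27 with no filter, 51 in a fit of these groups alone and 28 when each transcript was tested, and the higher share went from 29.6% to 54.4% with equal FPKM sums, which raised the median of all genes to 0.112.

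H2D against NCD makes the same comparison for the F1 offspring line. Acute phase and neutrophil genes rose. The serum amyloid genes Saa1 (ENSMUSG00000074115, chromosome 7, 46740497 to 46743181) and Saa2 went from 67.7 ± 23.6 to 5664 ± 3090 FPKM and from 45.6 ± 14.7 to 6534 ± 4094 FPKM (SD, n = 2 pools each). Of 29 acute phase genes 20 rose and 0 fell (26 and 1 adjusted over the list alone; median 1.40, camera adjusted p = 1.2e-24, adjusted p = 0.0502 with an estimated correlation), with Itih3 (1.71 ± 0.09), Itih4 (1.17 ± 0.11) and Serpina3n (1.68 ± 0.13) among those of smallest p. Orm2 (5.64 ± 0.57) and the metal-binding Mt2 (5.57 ± 0.87) were other large rises. All 12 of 12 neutrophil markers rose (12 and 0 adjusted over the list alone; median 3.11, camera adjusted p = 1.7e-14, adjusted p = 0.327 with an estimated correlation). The granule genes Ltf (3.53 ± 0.51), Mpo (3.11 ± 0.49), Camp (4.42 ± 0.73) and Ngp (5.03 ± 0.83) and the alarmin S100a8 (8.68 ± 6.05 to 232 ± 24.2 FPKM) were among them. Several, such as Ltf (0.0569 ± 0.0615 to 6.02 ± 1.66 FPKM) and Mpo (0.103 ± 0.0806 to 4.89 ± 2.01), passed the filter of 1 FPKM in 2 libraries only through H2D and H3D. The filter thus partly fixes the neutrophil count and median. Log2 changes of such members depend on the 0.5 FPKM added. Lcn2, which stands in both lists, rose to 1510 ± 415 FPKM. In the erythroid list 1 of 7, Hbb-bt, rose and 0 fell (6 and 0 adjusted over the list alone; median 1.42, camera adjusted p = 0.000669, adjusted p = 0.452 with an estimated correlation). In the macrophage list 5 of 23 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.84, camera adjusted p = 2.4e-10, adjusted p = 0.441 with an estimated correlation), including Trem2 (1.35 ± 0.19) and Ccr2 (0.93 ± 0.17).

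CAR and PXR type, NRF2 and fatty acid synthesis lists had lower medians in H2D. Of 23 CAR and PXR type genes 15 fell and 0 rose (19 and 0 adjusted over the list alone; median -1.54, camera adjusted p = 2.6e-17, adjusted p = 0.197 with an estimated correlation). Cyp3a11, a main drug-metabolising P450, fell from 1327 ± 89.4 to 164 ± 0.277 FPKM and Cyp2b10 by 2.93 on the log2 scale. Of 20 NRF2 targets 8 fell and 0 rose (13 and 1 adjusted over the list alone; median -0.79, camera adjusted p = 4.1e-09, adjusted p = 0.362 with an estimated correlation), including Ugdh (-1.18 ± 0.15) and Gsta2 (-2.73 ± 0.45). Of 19 fatty acid synthesis genes 5 fell and 0 rose (14 and 0 adjusted over the list alone; median -0.83, camera adjusted p = 1.6e-09, adjusted p = 0.197 with an estimated correlation), including Me1 (-2.75 ± 0.23) and ATP citrate lyase, Acly (-0.94 ± 0.15). Of 25 male-biased genes 11 fell and 0 rose (14 and 1 adjusted over the list alone; median -1.12, camera adjusted p = 1.7e-10, adjusted p = 0.421 with an estimated correlation). Acsl1 fell to 117 ± 12.9 FPKM (adjusted p = 0.00589) and Aldh2 to 701 ± 59.7 FPKM (adjusted p = 0.0318). Car3 (-2.94 ± 0.32) and Vil1 (-2.84 ± 0.37) were also among the 6 largest falls.

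In total 471 genes were called in H2D against NCD, 248 higher and 223 lower, with 2289 at an unadjusted p under 0.05. Of the 16 fixed genes 1 rose, 4 fell and 11 were not called. The count was 46 without NCD replicate 1, 22 without NCD replicate 2, 154 without H2D replicate 1 and 39 without H2D replicate 2, and 9 of 57 called named genes kept their call in all 10 fits that left out a pool. It was 250 with no filter, 795 in a fit of these groups alone and 234 when each transcript was tested, and the higher share went from 52.7% to 71.1% with equal FPKM sums, which raised the median of all genes to 0.101.

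H3D against NCD makes the comparison for the F2 offspring line, the longest ancestry on the diet. Male-biased genes fell. Hsd3b5 was 0.0923 ± 0.0287 FPKM in H3D against 54.5 ± 9.65 in NCD, and Cyp4a12a (ENSMUSG00000066071) was 0.555 ± 0.0443 against 83.5 ± 25.1 (SD, n = 2 pools each). Of 25 male-biased genes 22 fell and 0 rose (22 and 0 adjusted over the list alone; median -3.09, camera adjusted p = 1.4e-21, adjusted p = 0.257 with an estimated correlation). Others were Cyp2d9 (-3.45 ± 0.18) and the organic anion transporter Slco1a1 (-4.24 ± 0.26). Mup12, Mup11, Mup1, Mup15 and Mup17 had fitted falls of -8.12 to -6.92, with the reservation about Mup paralogs given above. Of 26 female-biased genes 2 rose, 3 fell and 21 were not called (median 0.06, 50% of members above 0, camera adjusted p = 0.376). Of 23 abundant secreted proteins of hepatocytes 3 rose, 7 fell and 13 were not called (median -0.11, 39.1% of members above 0, camera adjusted p = 0.303).

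Acute phase, metallothionein and neutrophil genes rose in H3D. Of 29 acute phase genes 21 rose and 2 fell (23 and 2 adjusted over the list alone; median 1.29, camera adjusted p = 2.4e-14, adjusted p = 0.174 with an estimated correlation). Lcn2 (ENSMUSG00000026822, chromosome 2, 32384637 to 32387739) went from 240 ± 57.4 to 2559 ± 125 FPKM. Mt2 (6.06 ± 0.87) and Mt1 (5.11 ± 0.61), which bind zinc and other metals, were among the 6 largest rises, with Saa2 (4.89 ± 0.72) and Chil3 (4.60 ± 0.63). All 12 of 12 neutrophil markers rose (12 and 0 adjusted over the list alone; median 3.47, camera adjusted p = 9.4e-11, adjusted p = 0.257 with an estimated correlation), with Ngp at 5.12 ± 0.83 and S100a8 at 4.86 ± 0.89. As in H2D, the filter partly fixes this count and median. In the erythroid list 4 of 7 rose and 0 fell (6 and 0 adjusted over the list alone; median 1.86, camera adjusted p = 0.000616, adjusted p = 0.417 with an estimated correlation), including the red cell membrane gene Slc4a1 (2.59 ± 0.43). In the macrophage list 7 of 23 rose and 0 fell (14 and 0 adjusted over the list alone; median 0.71, camera adjusted p = 3.8e-06, adjusted p = 0.447 with an estimated correlation). In the cell cycle list 10 of 24 rose and 1, Tk1, fell (13 and 1 adjusted over the list alone; median 0.94, camera adjusted p = 4.4e-05, adjusted p = 0.390 with an estimated correlation). Among members with a mean of at least 5 FPKM the median was -0.22 and the call ended, so this direction held for low-abundance members such as Ccnb2 (1.16 ± 0.229 to 5.01 ± 0.933 FPKM). Of the tumour and fetal markers 5 of 19 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.72, camera adjusted p = 0.00123, adjusted p = 0.257 with an estimated correlation). Cd24a (1.63 ± 0.24) and Tff3 (1.30 ± 0.22) rose, and Afp fell by 1.45 on the log2 scale (adjusted p = 0.0407).

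Lists of fatty acid oxidation, alcohol and aldehyde oxidation, bile acids, drug metabolism and fatty acid synthesis had lower medians in H3D. Of 27 PPARα and fatty acid oxidation genes 17 fell and 1 rose (21 and 1 adjusted over the list alone; median -0.62, camera adjusted p = 1.8e-08, adjusted p = 0.352 with an estimated correlation). Acsl1 fell from 276 ± 43.3 to 69.4 ± 0.789 FPKM (adjusted p = 0.000237) and the peroxisomal thiolase Acaa1b by 2.94 on the log2 scale. Of 16 alcohol and aldehyde dehydrogenases 14 fell and 0 rose (15 and 0 adjusted over the list alone; median -0.91, camera adjusted p = 1.5e-10, adjusted p = 0.257 with an estimated correlation). Aldh2 fell from 1095 ± 34.8 to 508 ± 4.77 FPKM (adjusted p = 0.00181) and Aldh1a1 by 2.01 on the log2 scale. Of 20 bile acid genes 13 fell and 0 rose (13 and 0 adjusted over the list alone; median -0.90, camera adjusted p = 5.4e-09, adjusted p = 0.257 with an estimated correlation). Cyp8b1 (-2.97 ± 0.42), the bile salt export pump Abcb11 (-0.90 ± 0.13) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-1.82 ± 0.32), were among them. Of 23 CAR and PXR type genes 17 fell and 0 rose (17 and 0 adjusted over the list alone; median -1.56, camera adjusted p = 2.2e-12, adjusted p = 0.257 with an estimated correlation). Of 20 genes of pericentral hepatocytes 11 fell and 1 rose (12 and 2 adjusted over the list alone; median -0.96, camera adjusted p = 9.4e-08, adjusted p = 0.257 with an estimated correlation), including Cyp2e1 (-2.66 ± 0.22) and glutamine synthetase, Glul (-1.38, adjusted p = 0.00238). Of 19 fatty acid synthesis genes 9 fell and 0 rose (12 and 0 adjusted over the list alone; median -0.81, camera adjusted p = 4.5e-06, adjusted p = 0.257 with an estimated correlation), and 8 of 13 mitochondrially encoded genes fell and 0 rose (12 and 0 adjusted over the list alone; median -0.61, camera adjusted p = 9.8e-07, adjusted p = 0.257 with an estimated correlation). The lists of lipid droplet genes (2 of 17 rose and 4 fell, camera adjusted p = 0.179) and glucose metabolism (1 of 29 rose and 6 fell, camera adjusted p = 0.220) did not pass.

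In total 1724 genes were called in H3D against NCD, 583 higher and 1141 lower, with 3458 at an unadjusted p under 0.05. Of the 16 fixed genes 2 rose, 6 fell and 8 were not called. The count was 705 without NCD replicate 1, 506 without NCD replicate 2, 929 without H3D replicate 1 and 955 without H3D replicate 2, and 51 of 81 called named genes kept their call in all 10 fits that left out a pool. With equal FPKM sums the count was 2657 and the higher share went from 33.8% to 74.7%, with the median of all genes at 0.201.

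**Figure D2:**
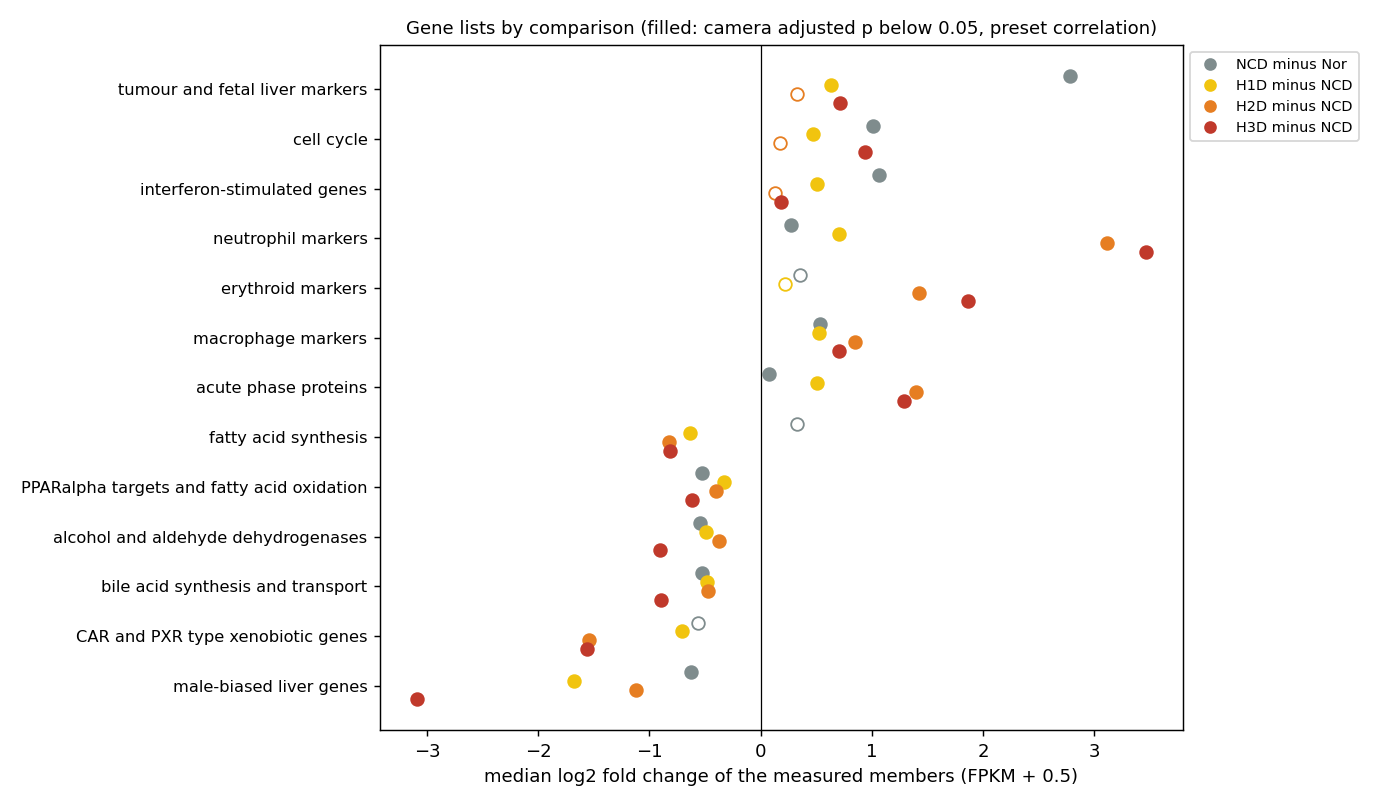
Median log2 fold change of the measured members of 13 gene lists (x axis, FPKM with 0.5 added) in NCD against Nor and in each high-fat group against NCD (colours). Filled points passed camera at an adjusted p below 0.05 with the preset correlation. With an estimated correlation, 1 of these calls held, tumour and fetal liver markers in NCD against Nor. Neutrophil markers lay at 3.11 in H2D and 3.47 in H3D, and male-biased genes at -3.09 in H3D.

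The mean of the 3 high-fat groups against NCD gave 1359 calls, 489 higher and 870 lower (3190 at an unadjusted p under 0.05). Mt2 (5.02 ± 0.71), Mt1 (4.23 ± 0.50), Saa1 (3.99 ± 0.49), Lcn2 (2.57 ± 0.17), the neutrophil elastase Elane (2.35 ± 0.46) and the hepatokine Fgl1 were the largest rises under the naming rule. Falls were led by Mup12, Mup15, Mup17 and Mup1, Cyp4a12a (-3.91 ± 0.24) and Hsd3b5 (-3.83 ± 0.28). Acsl1 fell by 1.37 (adjusted p = 0.000848), Aldh2 by 0.75 (adjusted p = 0.00568) and Scd1, the stearoyl-CoA desaturase, by 1.34 on the log2 scale (adjusted p = 0.0314). Trem2 rose by 1.35 (adjusted p = 0.00292). Of the 16 fixed genes 1 rose, 5 fell and 10 were not called. The count was 150 without NCD replicate 1, 96 without NCD replicate 2 and 715 without H2D replicate 2, with 23 of 81 called named genes kept in all 10 fits that left out a pool, and the higher share went from 36.0% to 73.1% with equal FPKM sums, which raised the median of all genes to 0.138.

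Called in all 3 high-fat groups against NCD were 18 higher and 46 lower genes, 64 together. Lcn2, Serpina3n, Itih3, Cp, Mpeg1, Trem2, Pglyrp1 and Map3k6 were among the higher ones, and Acsl1, Me1, Cyp1a2, Ces2a, Cyp4a12a, Hsd3b5, Cyp2d9 and Slco1a1 among the lower ones. H2D and H3D shared 192 higher and 201 lower calls, where independent lists of those sizes would share 12.5 and 22.0. The groups share the NCD pools, which alone makes their changes correlate (0.502 in 50 simulations with no change, 0.793 measured). The covariance of the log2 changes was 0.0297 in those simulations and 0.2126 measured. How many of the shared calls come from this was not tested. The count of 64 was 0 without NCD replicate 1 or NCD replicate 2, 2 without H1D replicate 1, 25 and 15 without H2D replicates 1 and 2, 24 and 41 without H3D replicates 1 and 2, and 124 without Nor replicate 1 or Nor replicate 2. It was 42 with a pseudocount of 0.1, 19 with no filter and 40 in fits of the groups compared.

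H2D against H1D asks whether the F1 offspring line differs from the first on the same diet. Some acute phase genes did: Saa2 was 104 ± 68.1 FPKM in H1D and 6534 ± 4094 in H2D, Saa1 170 ± 80.9 and 5664 ± 3090, and Orm2 50.3 ± 43.9 and 1053 ± 366 (SD, n = 2 pools each). In that list 5 of 29 rose and 0 fell (20 and 1 adjusted over the list alone; median 0.78, camera adjusted p = 3.5e-17, adjusted p = 0.112 with an estimated correlation). Reg3b (2.85 ± 0.35), the ferritin receptor Scara5 (2.34 ± 0.29) and Dnajc12 (2.29 ± 0.25) also rose and Prom2 fell (-1.86 ± 0.22), each with adjusted p = 0.0438. Neutrophil markers had a median of 2.61 with 0 of 12 called (12 and 0 adjusted over the list alone; camera adjusted p = 7.7e-17, adjusted p = 0.327 with an estimated correlation). The reservation about the filter for neutrophil markers given above applies. In total 17 genes were called, 16 higher and 1 lower (1125 at an unadjusted p under 0.05), and 0 of the 16 fixed genes. Leaving out NCD replicate 1, NCD replicate 2, H1D replicate 1, H2D replicate 1 or H2D replicate 2 gave 0 calls (956, 957, 590, 900 and 669 genes at an unadjusted p under 0.05), Nor replicates 1 and 2 gave 28 and 35 and H3D replicates 1 and 2 gave 30 and 29, so that 0 of 8 called named genes kept their call throughout. With limma the count was also 0 with a pseudocount of 0.1 (1090 at an unadjusted p under 0.05), with no variance trend (1136) and when each transcript was tested (1524 transcripts). It was 1 in a fit of these groups alone, 3 with no filter and 8 with replicate number as a block.

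H3D against H2D asks the same of the next generation. Male-biased genes were lower in H3D: Hsd3b5 was 15.0 ± 6.97 FPKM in H2D and 0.0923 ± 0.0287 in H3D, and Cyp4a12a 14.2 ± 4.49 and 0.555 ± 0.0443 (SD, n = 2 pools each). The fall was not stepwise over the generations. Pool medians of the male-biased list against NCD were -1.73 and -1.53 in H1D, -1.02 and -1.14 in H2D and -3.12 and -3.12 in H3D. In that list 12 of 25 fell and 0 rose (23 and 0 adjusted over the list alone; median -2.21, camera adjusted p = 5.6e-32, adjusted p = 0.187 with an estimated correlation). Of 20 periportal hepatocyte genes 2 fell and 0 rose (13 and 1 adjusted over the list alone; median -0.81, camera adjusted p = 2.7e-10, adjusted p = 0.154 with an estimated correlation). They were the tyrosine aminotransferase Tat (-1.12 ± 0.17) and Etnppl (-2.52 ± 0.40). The glutathione transferase Gstm3 (2.51 ± 0.39), Tekt5 (2.42 ± 0.39), the antioxidant Srxn1 (1.49 ± 0.17), Map3k6 (1.01 ± 0.15), Ica1 (0.97 ± 0.11) and Shc2 (0.88 ± 0.12) rose. In total 59 genes were called, 6 higher and 53 lower (1478 at an unadjusted p under 0.05), and 1 of the 16 fixed genes fell. The count was 105 without either Nor pool, 34 and 35 without NCD replicates 1 and 2, 120 without either H1D pool, 17 and 18 without H2D replicates 1 and 2, and 17 and 32 without H3D replicates 1 and 2, and 5 of 21 called named genes kept their call throughout. It was 36 with no filter and 39 with no variance trend.

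H3D against H1D spans the generations. Neutrophil genes and the globin gene Hbb-bt were higher and hepcidin lower in H3D: Mpo was 0.311 ± 0.419 FPKM in H1D and 7.04 ± 4.55 in H3D, Hbb-bt 59.0 ± 2.57 and 250 ± 133, and Hamp, the liver hormone that limits iron uptake, had a log2 change of -4.12 ± 0.49 (FPKM with SD, n = 2 pools each). Of 12 neutrophil markers 2 rose and 0 fell (12 and 0 adjusted over the list alone; median 2.74, camera adjusted p = 8.9e-18, adjusted p = 0.240 with an estimated correlation). Here too some of these markers passed the filter only through H2D and H3D. In the erythroid list 1 of 7, Hbb-bt, rose and 0 fell (6 and 0 adjusted over the list alone; median 1.655, camera adjusted p = 1.3e-08, adjusted p = 0.315 with an estimated correlation). Of 25 male-biased genes 12 fell and 0 rose (18 and 0 adjusted over the list alone; median -1.60, camera adjusted p = 5.1e-20, adjusted p = 0.240 with an estimated correlation). Of 20 pericentral genes 5 fell and 0 rose (10 and 0 adjusted over the list alone; median -0.70, camera adjusted p = 8.6e-12, adjusted p = 0.240 with an estimated correlation), with Cyp2e1 at -2.03 ± 0.22 and Glul at -1.21 ± 0.17. The chemokine Cxcl14 (3.03 ± 0.31) and Cyp17a1 (2.27 ± 0.27) rose and Car3 fell (-3.58 ± 0.32). Acsl1 fell by 1.05 on the log2 scale (adjusted p = 0.0189), and Aldh2 differed by -0.62 without passing (adjusted p = 0.0898). In total 70 genes were called, 16 higher and 54 lower (1332 at an unadjusted p under 0.05), and 3 of the 16 fixed genes fell. The count was 111 and 114 without Nor replicates 1 and 2, 32 without either NCD pool, 28 and 24 without H1D replicates 1 and 2, and 16 and 12 without H3D replicates 1 and 2, and 3 of 27 called named genes kept their call throughout. It was 15 in a fit of these groups alone.

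Noncoding transcripts were compared in the same livers. H19, the imprinted transcript of fetal liver, was 0.0359 ± 0.0257 FPKM in Nor and 33.1 ± 19.03 in NCD (SD, n = 2 pools each; log2 change 5.85 ± 0.49, adjusted p = 0.000807). The antisense transcript Gm10680 rose from 46.2 ± 4.95 to 943 ± 147 FPKM, the unannotated LNC_000206 from 6.15 ± 0.603 to 77.2 ± 6.38, and TUCP_000223 from 0.607 ± 0.237 to 10.9 ± 0.133. Gm15622 fell from 8.76 ± 1.31 to 1.31 ± 0.245 FPKM. Malat1, Neat1 and Meg3 transcripts were not called, with adjusted p from 0.224 to 0.868. In NCD against Nor 26 of 1493 transcripts were called, 21 higher and 5 lower (278 at an unadjusted p under 0.05). That count was 7 without NCD replicate 1, 15 without NCD replicate 2 and 2 in a fit of these groups alone.

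For the mean of the high-fat groups against NCD, 32 noncoding transcripts were called, 6 higher and 26 lower (276 at an unadjusted p under 0.05). Gm13021 fell from 8.17 ± 0.243 FPKM (n = 2 pools) to 0.596 ± 0.714 (n = 6 pools), TUCP_000163 from 16.3 ± 0.0154 to 2.93 ± 2.58 and Gm13775 from 46.3 ± 7.21 to 9.22 ± 7.03. Gm17104 rose by 1.29 ± 0.23 on the log2 scale and an antisense transcript of Apol7d by 1.04 ± 0.20. The count was 1 and 2 without NCD replicates 1 and 2, 5 without H1D replicate 1, 11 and 8 without H2D replicates 1 and 2, 7 and 14 without H3D replicates 1 and 2, and 56 and 54 without Nor replicates 1 and 2. It was 13 with a pseudocount of 0.1, 14 with replicate number as a block, 50 in a fit of these groups alone and 64 in a joint fit with mRNA. In H3D against H1D 1 transcript, TUCP_000301, was called (4.08 ± 1.35 to 0.493 ± 0.0601 FPKM; 147 at an unadjusted p under 0.05) and the count was 2 without H1D replicate 1 and 0 with limma without either pool of Nor, NCD, H2D or H3D. It was 2 with a pseudocount of 0.1 and 3 with the stricter filter or in a joint fit with mRNA. With a pseudocount of 1, no variance trend, replicate number as a block or a fit of these groups alone it was 0.

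Small RNA libraries show which mature miRNAs differed, without replicates. In NCD against Nor 57 of 290 miRNAs were at least 2-fold higher and 0 at least 2-fold lower. The one-sided split depends on scaling to the library total: TMM factors, which moved the median log2 ratio by -0.447, gave 44 higher and 9 lower. miR-146b-5p was counted 883 times in Nor and 186063 times in NCD, or 109 RPM (95% interval 102 to 117) and 25980 (25860 to 26100), a 237-fold ratio with 0.5 RPM added to each side, as in all ratios here. The 30 miRNAs fixed as the Dlk1-Dio3 imprinted cluster, which is active in fetal tissue, supplied 22 of the 57. With at least 20 reads 28 of the 30 were measured, and 28 were at least 2-fold higher, with a median log2 ratio of 3.71, at percentile 100 of random lists. miR-409-3p was 26.1-fold, miR-543-3p 22.8-fold, miR-134-5p 22.6-fold and miR-494-3p 22.5-fold higher. The liver tumour list had a median of 1.28 (percentile 99.98), with miR-34a-5p, a p53-induced miRNA, at 32.2 RPM in Nor and 143 in NCD. miR-122-5p, the main hepatocyte miRNA, was 26.0% of reads in Nor and 22.1% in NCD.

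Against NCD, H1D had 3 miRNAs at least 2-fold higher and 37 lower of 297, H2D 8 and 42 of 293, and H3D 6 and 52 of 286. With TMM factors these were 4 and 35, 11 and 42, and 11 and 44. The Dlk1-Dio3 cluster had medians of -1.18, -1.71 and -2.41, each at percentile 0 of random lists, and supplied 18, 22 and 22 of the miRNAs that passed. Members of the cluster lie at 1 locus and are not independent, which the random lists do not allow for. These comparisons and NCD against Nor also share the single NCD library, so they are not separate evidence. miR-127-3p of that cluster was 90.0 RPM in Nor, 1502 in NCD, 546 in H1D, 330 in H2D and 87.0 in H3D. miR-341-3p went from 82.2 RPM in NCD (95% interval 75.7 to 89.2) to 3.64 in H3D (2.36 to 5.38), and miR-434-3p from 97.7 to 4.52. In H1D, miR-375-3p was 8.15-fold higher than in NCD, and miR-881-3p (-1.91) and miR-592-5p (-1.82) had the lowest log2 ratios. miR-210-3p, induced by low oxygen, was 14.9 RPM in NCD, 94.9 in H2D and 66.3 in H3D. miR-802-5p was 34.4 in NCD and 102 in H2D. In H3D against H1D 3 of 276 were at least 2-fold higher and 34 lower (7 and 26 with TMM factors), and the cluster median was -1.23.

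miR-27a-3p was 597 RPM in Nor (95% interval 581 to 614), 798 in NCD (778 to 819), 988 in H1D (966 to 1011), 1075 in H2D (1053 to 1098) and 1015 in H3D (991 to 1039), under the 2-fold rule in every comparison made. Its log2 ratio in NCD against Nor was 0.418 with library totals and -0.035 with TMM factors, so the difference between these groups did not outlast the change of scaling. Against NCD the ratios were 0.308 in H1D, 0.430 in H2D and 0.346 in H3D, and 0.411, 0.483 and 0.623 with TMM factors. miR-21a-5p was 101000 in Nor, 157900 in NCD, 168100 in H1D, 208300 in H2D and 259000 in H3D, when it was 25.9% of reads. For miR-21a-5p in NCD against Nor the log2 ratio was 0.645 with library totals and 0.191 with TMM factors. miR-192-5p and miR-221-3p stayed under the rule with either scaling. Counts under the rule follow the read minimum: from 20 reads they were 87 in NCD against Nor and 97 in H3D against NCD, and from 500 reads 32 and 32.

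**Figure D3:**
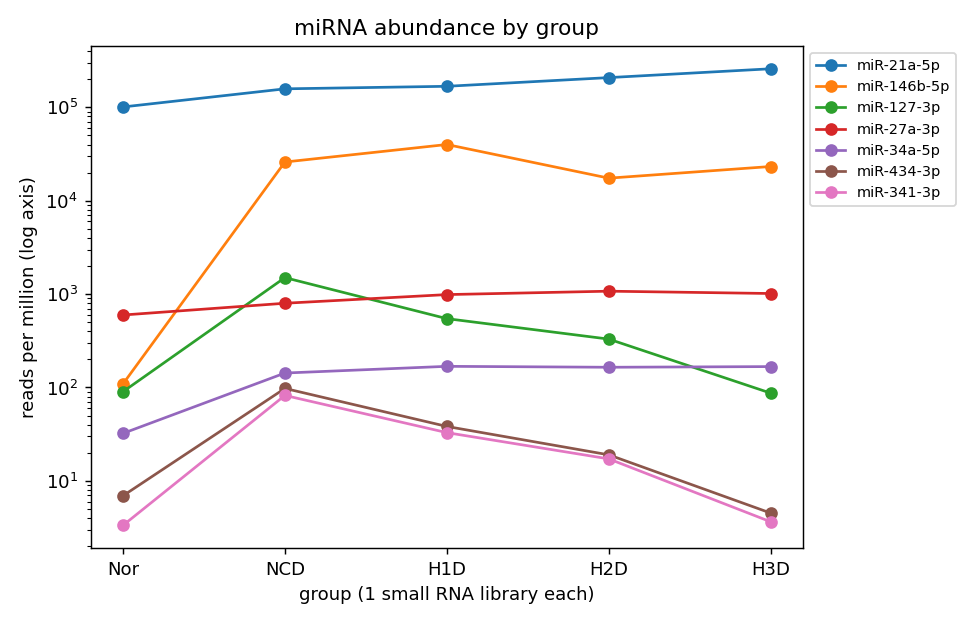
RPM (log axis) of 7 miRNAs in the 1 small RNA library of each group. miR-146b-5p was 109 in Nor and between 17450 and 40010 in the DEN groups, and the Dlk1-Dio3 members miR-127-3p, miR-434-3p and miR-341-3p were highest in NCD and near their Nor level in H3D (87.0, 4.52 and 3.64).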

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

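The high-fat groups differed from each other when compared directly with limma, 2 pools each. The gene lists given here passed camera with its preset correlation and fry, a choice made after the tables were seen, and with an estimated correlation 0 of these list calls held. The tests of explanations in the last paragraphs were also chosen after the results were seen. In H2D against H1D 17 genes differed, and the count was 0 without either NCD pool, H1D replicate 1 or either H2D pool. Saa2 (5.98), Saa1 (5.02), Orm2 (4.66), Reg3b (2.85), Scara5 (2.34) and Dnajc12 (2.29) were higher and Prom2 (-1.86) lower in H2D on the log2 scale. List medians were 0.78 for acute phase proteins, 0.58 for periportal hepatocyte genes (camera adjusted p = 1.0e-08, adjusted p = 0.119 with an estimated correlation) and -0.18 for imprinted genes (camera adjusted p = 0.0476, adjusted p = 0.403 with an estimated correlation), whose call ended when any pool other than NCD replicate 1 was left out.

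In H3D against H2D 59 genes differed, 17 without H2D replicate 1 or H3D replicate 1, 18 without H2D replicate 2, 32 without H3D replicate 2, 34 and 35 without NCD replicates 1 and 2, 105 without either Nor pool and 120 without either H1D pool. Gstm3 (2.51), Tekt5 (2.42), Srxn1 (1.49), Map3k6 (1.01), Ica1 (0.97) and Shc2 (0.88) were higher in H3D. Mup11 (-6.17), Mup12 (-5.66), Mup1 (-5.38), Mup14 (-5.03), Mup17 (-4.94) and Mup7 (-4.91) were lower, with reads that can be shared among these paralogs. List medians were -2.21 for male-biased genes and -0.81 for periportal genes.

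In H3D against H1D 70 genes differed, 12 and 16 without H3D replicates 2 and 1, 24 and 28 without H1D replicates 2 and 1, 32 without either NCD pool, and 111 and 114 without Nor replicates 1 and 2. Mpo (3.18), Cxcl14 (3.03), Cyp17a1 (2.27), Scara5 (2.21), Hbb-bt (1.96) and Lcn2 (1.82) were higher in H3D, and Mup12 (-4.97), Mup11 (-4.48), Hamp (-4.12), Mup1 (-3.73), Mup19 (-3.73) and Car3 (-3.58) lower. List medians were 2.74 for neutrophil markers, 0.58 for acute phase proteins, -0.70 for pericentral genes, -0.91 for CAR and PXR type genes and -1.60 for male-biased genes, with adjusted p = 0.169 for acute phase proteins and 0.240 for each of the other 4 with an estimated correlation.

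Neutrophil and erythroid markers were higher in H2D and H3D than in NCD. The neutrophil list also passed camera in H1D, with a lower median of 0.71 and pools at 0.01 and 1.36, and not without H1D replicate 2. In each of the 4 pools the neutrophil median exceeded the globin median by at least 1.56 on the log2 scale, which argues against more blood of unchanged composition in the tissue, and in H3D it lay 2.76 above the highest median of the other cell types (0.71, macrophages), which argues against a smaller share of hepatocytes as the whole cause. The neutrophil median includes members that passed the filter only through H2D and H3D, which favours a high value. For the erythroid genes, miR-451a, miR-144-3p and miR-486a-5p of red cells had medians of 0.26 in H2D and 0.56 in H3D, where globin genes had 1.47 and 1.86, and with 1 small RNA pool per group more blood in the tissue stays open for them. Neutrophils within the tissue, or blood richer in neutrophils, may account for the pattern. Both stay open. H1D mice ate the same diet, and the lowest neutrophil median of an H2D or H3D pool lay 1.43 above the highest of an H1D pool. Pools of a high-fat group differed by up to 1.35, nearly as much, and 2 pools do not bound the spread between animals. This gap therefore cannot decide on the diet of the mice as the whole cause of the neutrophil pattern, and the diet stays open. For the erythroid genes that gap was 0.30 against a range of up to 1.38, so the diet stays open there too. The ancestry of the mice, which cannot be told apart from their cohort, stays open for both and was not tested.

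Male-biased genes were lower in H3D than in NCD, with a median of -3.09. Abundant secreted proteins of hepatocytes had a median of -0.11, which argues against a smaller share of hepatocytes as the whole cause. That list mixes the acute phase gene Hpx (2902 to 7671 FPKM) with members that were lower, such as Ttr (4521 to 1890 FPKM). Other lists of hepatocyte genes had lower medians in H3D, as given above, so a smaller share as part of the cause stays open. The 17 members outside the Mup family had a median of -2.70, with 15 below -1, and with equal FPKM sums the list median was -2.88 (camera adjusted p = 1.4e-33 with the preset correlation), so shared Mup reads or the FPKM scale are unlikely as the whole cause. Female-biased genes had a median of 0.06 in H3D with members moving both ways, so they did not rise as a set against NCD. Their median was already 1.35 in NCD against Nor. The lack of a further rise therefore cannot decide on a switch from male to female expression. A switch of all or some of these genes stays open. Against NCD the median of the female-biased genes was 0.74 in H1D, where the list passed camera, and 0.045 in H2D, where it did not. H1D and H2D mice ate the same diet, and their lowest pool median lay 1.39 above the highest of H3D. Pools of a high-fat group differed by up to 0.20. That range leaves out Nor, whose pools differed more for some members and little for others. Mup7 was 15970 ± 12560 FPKM in Nor, Mup1 1841 ± 1478 and Hsd3b5 123 ± 51.0, while Keg1 was 195 ± 7.48 and Mup21 333 ± 7.75. The list median of the Nor pools was not computed, so pools of a group may differ by more than 0.20. Judged by the range of the high-fat groups alone, the gap argues against the diet of the mice as the whole cause, though not as part of it. A change in the hormones that set these genes and the ancestry of the mice, which cannot be told apart from their cohort, are open explanations that were not tested.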

How the results depend on the processing

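Leaving out 1 pool at a time, with its partner assumed to vary like the other groups, gave 256 to 2366 mRNA genes in NCD against Nor, 0 to 184 in H1D, 22 to 662 in H2D, 506 to 2171 in H3D and 96 to 1747 in the mean of the high-fat groups against NCD, 0 to 35 in H2D against H1D, 17 to 120 in H3D against H2D and 12 to 114 in H3D against H1D. Noncoding transcripts numbered 7 to 30 in NCD against Nor, 1 to 56 in the mean of the high-fat groups and 0 to 2 in H3D against H1D, and genes called in all 3 high-fat groups 0 to 124. Gene lists passing camera numbered 21 to 25, 18 to 26, 15 to 19, 17 to 20, 19 to 23, 18 to 20, 17 to 22 and 14 to 18 in the same order of comparisons. Fewer samples and residual degrees of freedom are part of these changes by construction. Direction and call held in every setting that tested the result for 98 of 152 list results, 127 of 391 named gene results and 2 of 17 noncoding results. The stricter filter tested 324 of these named gene results and 12 of these noncoding results. For miRNAs the rule was another: in 19 of 75 results the log2 ratio stayed within its Poisson interval in every setting. Settings of the read minimum leave that ratio unchanged, so only TMM scaling and 5 RPM added could move it. A miRNA could leave that interval, which covers counting error only, without a change of direction or of 2-fold status. The direction turned in 10 list results (for a list, the direction of camera) and 0 named gene results. The depth of the long RNA libraries is unknown, so what depth limits there cannot be stated, and for miRNAs a count of 0 allows up to 3 reads.

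For changes by setting the cause was not tested, except that a fit of fewer groups has fewer samples and a transcript fit more tests. With a pseudocount of 0.1 there were 52 genes in H1D against NCD, 0 in H2D against H1D with limma (1090 at an unadjusted p under 0.05), 13 noncoding transcripts in the mean of the high-fat groups, 2 in H3D against H1D and 42 genes shared by all 3 high-fat groups. With a pseudocount of 1 there were 0 noncoding transcripts in H3D against H1D. With no filter there were 27 genes in H1D and 250 in H2D against NCD, 3 in H2D against H1D, 36 in H3D against H2D and 19 shared. With the stricter filter the camera direction of the cell cycle list turned and its call was lost, with medians of 0.038 in H1D, -0.221 in H3D and -0.127 in the mean against NCD and -0.149 in H3D against H1D, and noncoding transcripts in H3D against H1D numbered 3. Quantile scaling gave 652 genes in NCD against Nor, where the neutrophil median went from 0.272 to -0.248. In fits of the groups compared there were 681 genes in NCD against Nor, 51 in H1D and 795 in H2D against NCD, 1 in H2D against H1D and 15 in H3D against H1D, with 2, 50 and 0 noncoding transcripts in the 3 noncoding comparisons and 40 shared genes.

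With no variance trend there were 0 genes in H2D against H1D with limma (1136 at an unadjusted p under 0.05), 39 in H3D against H2D and 0 noncoding transcripts in H3D against H1D. With replicate number as a block there were 8 genes in H2D against H1D and 14 and 0 noncoding transcripts in the mean of the high-fat groups and in H3D against H1D. Equal FPKM sums, a setting chosen after seeing the data, gave 2657 genes in H3D against NCD. An adjusted p below 0.1 gave 239 shared genes. Testing each transcript gave 914 genes in NCD against Nor, 28 in H1D and 234 in H2D against NCD and 0 in H2D against H1D. A joint fit with mRNA gave 64 noncoding transcripts in the mean of the high-fat groups and 3 in H3D against H1D. With an estimated correlation between genes camera passed 1 list in NCD against Nor and 0 in H1D, 0 in H2D, 0 in H3D and 0 in the mean against NCD, and 0, 0 and 0 between high-fat groups. From 20 reads 87 miRNAs were 2-fold different in NCD against Nor, 63 in H1D and 97 in H3D against NCD and 65 in H3D against H1D. From 500 reads the counts were 32 in NCD against Nor, 22, 28 and 32 in H1D, H2D and H3D against NCD and 20 in H3D against H1D.

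With 1 pool left out, the direction of the camera test turned for 6 list results. In H2D against H1D these were cell cycle without H1D replicate 1 (median 0.018, range over the 10 fits -0.589 to 0.018) and endothelial markers without H2D replicate 1 (-0.008, range -0.258 to 0.015). The others were interferon-stimulated genes in H3D against NCD without H3D replicate 1 (-0.098, range -0.098 to 0.409), cholesterol synthesis in H3D against H2D without H3D replicate 1 (-0.176, range -0.176 to 0.544) and in H3D against H1D without H3D replicate 2 (0.194, range -0.499 to 0.194), and macrophage markers in H3D against H1D without H3D replicate 2 (-0.157, range -0.157 to 0.447).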

Other observations

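Further gene groups moved beside those described. In NCD against Nor 2 of 6 genes of MHC class II presentation rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 1.23 (camera adjusted p = 0.000817, adjusted p = 0.443 with an estimated correlation). Of 17 cytokines and chemokines 5 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 0.000175, adjusted p = 0.443 with an estimated correlation). In H1D against NCD interferon-stimulated genes had a median of 0.51 with 0 of 29 called by limma (10 and 0 adjusted over the list alone; camera adjusted p = 9.0e-11, adjusted p = 0.407 with an estimated correlation). Alcohol and aldehyde dehydrogenases had a median of -0.49 in H1D with 0 of 16 called (12 lower and 0 higher adjusted over the list alone; camera adjusted p = 5.4e-09, adjusted p = 0.323 with an estimated correlation). In H2D 5 of these 16 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 2.9e-07, adjusted p = 0.421 with an estimated correlation). Of 24 cholesterol synthesis genes 3 fell and 0 rose in H2D (10 and 0 adjusted over the list alone), with a median of -0.71 (camera adjusted p = 2.7e-08, adjusted p = 0.444 with an estimated correlation). Among small RNAs, blood and immune cell miRNAs had a median log2 ratio of 0.89 in NCD against Nor with library totals, at percentile 99.92 of random lists. TMM factors, which moved the median of all miRNAs by -0.447 in this comparison, were not applied to this list.

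The tests in this paragraph were chosen after the results were seen. miRNAs of the Dlk1-Dio3 cluster were higher in NCD than in Nor and lower in H3D than in NCD, in 1 library per group. With TMM factors the cluster median in H3D against NCD was -2.15, against -2.41 with library totals, which argues against scaling to the library total as the whole cause. Of 3 long transcripts of the locus, 2 (Meg3 and Rian, not Mirg) were higher in both NCD pools than in every Nor and H3D pool. Rian was 5.54 and 18.7 FPKM in the NCD pools, 1.36 and 0.183 in Nor and 1.45 and 0.363 in H3D. It was 7.86 and 2.39 in H1D and 0.463 and 4.61 in H2D, so the higher H1D pool lay above the lower NCD pool. Pools of a group differed several-fold, a spread that 1 small RNA pool per group cannot show for the miRNAs. No transcript of these genes was called by limma in NCD against Nor (adjusted p from 0.142 to 0.538). A change in transcription of the locus may contribute and stays undecided.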
